A study of Homo sapiens with 6 samples.

How the data were processed

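Gene expression was measured by RNA sequencing in 6 libraries of pulmonary arterial adventitial fibroblasts: 3 treatments of 24 h (vehicle, doxorubicin and Nutlin-3) with 2 replicates each. Per the labels, total RNA was purified with RNeasy columns, libraries were made with the NEBNext Ultra II directional kit, and the processing named BWA, DESeq2, hg38 and GRCh38 without versions or the role of each. The labels do not say how RNA was selected or whether reads were counted by strand. The authors deposited 1 table of raw counts per gene, 1 column per library, which by its name came from SeqMonk, and whose whole numbers were used as they stand. The authors also deposited DESeq2 tables for each treatment against vehicle, whose columns per the file headers are a p value, an FDR, a log2 fold change and a shrunken log2 fold change. Those tables list only genes with an FDR under 0.05, and their log2 values are treated over control by the sign of CDKN1A, GDF15 and MKI67 in the counts.

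The count table has 35858 genes, 27 of them with a name that reads as a date. Of these, 33224 (92.7%) match GENCODE 29 in name and position, and that annotation gave exonic lengths, GC content and gene types. Overlapping genes were found from the positions and strands in the count table. Genes on the Y chromosome, XIST and TSIX were left out of all tables and totals. Total counts ran from 24486872 to 29703404. The 13 mitochondrially encoded mRNA genes had 0 counts in all libraries and were not tested.

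Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered by filterByExpr with treatment as the group, which left 16224, and scaled by TMM. The model held treatment alone, fitted to all 6 libraries with 3 residual degrees of freedom, and the quasi-likelihood F test was run for doxorubicin against vehicle, Nutlin-3 against vehicle and doxorubicin against Nutlin-3. The p were adjusted by Benjamini and Hochberg with a threshold of 0.05, and CPM used for levels are TMM-scaled. Per the labels, replicates with the same number come from the same donor, so a model with donor added (2 residual degrees of freedom) was run beside it. As a check of that pairing, deviations from group means correlated across genes between same-numbered replicates at 0.719 (vehicle and doxorubicin), 0.885 (vehicle and Nutlin-3) and 0.730 (doxorubicin and Nutlin-3), where genes are not independent replicates. Models, lists, the rule for naming genes and the alternatives were fixed before the data were examined, unless said otherwise.

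Gene lists were tested by camera in limma 3.58.1 with a preset correlation between genes of 0.01, two-sided, adjusted over 21 lists. They were p53 targets, G2 and mitosis, DNA replication, replication-dependent histones, homologous recombination and Fanconi, the BCL2 family, extracellular matrix, contractile, secreted inflammatory, interferon-stimulated, BMP and TGF-beta pathway, cholesterol synthesis, immediate early, stress response, YAP target and ribosomal protein genes. Markers of adventitial fibroblasts, endothelium, smooth muscle and pericytes, epithelium and leukocytes completed them. Camera was repeated with a correlation estimated from the data, under which no list call held in any comparison, and fry was run as well. In that version camera refers its statistic to the residual degrees of freedom, 3 or 2 with donor, which leaves little power. For histone genes after doxorubicin with donor, the estimated correlation was 0.0105, near the preset. Their adjusted p still went from 2.58e-14 to 0.329, so a lost call does not show that correlation between genes made it. The p53 and BCL2 lists share 3 genes. Median, mean and direction in camera differed in sign for adventitial and endothelial markers after doxorubicin, and for stress response, smooth muscle and pericyte, and leukocyte genes after Nutlin-3. The same held for secreted inflammatory, BMP and TGF-beta pathway, and endothelial genes between the treatments, and none of these lists passed in camera there.

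Named genes were the 8 with the largest fold change in each direction for each treatment over vehicle, and 5 between treatments. They had to be called, to have the same direction in both donors, at least 5 CPM in a group and an assigned symbol. MDM2, CDKN1A and up to 4 members of each described list with the smallest p were added. Some genes that the rule takes are not used here. Applying the rule with donor in the model, and naming POLK, were decided after the values were seen. A gene at 0 counts in a group is given as a bound against 3 counts over the group, and one at 1 to 3 counts as a count ratio with a 95% interval. Genomic span was end minus start, set against log2 fold changes by Spearman's rho.

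Alternatives were DESeq2 size factors and upper-quartile scaling, no filter beyond 1 count, at least 10 counts in every library of a group, the DESeq2 1.42.0 Wald test, the donor model, the 2 compared groups alone, each library left out in turn, a fold of at least 2, an adjusted p under 0.01, and exonic length in place of span. For the shared vehicle libraries, 20 simulations drew all 6 libraries, vehicle included, from the fitted vehicle means of their donor, without treatment effects. Each simulated pair of comparisons shared the simulated vehicle libraries. The tests were also tested on simulated data with 200 changed genes among 15021 tested. The changed genes were drawn from those with a mean of at least 5 CPM. Spread came from the donor model and each change was the same in both donors, so the rates below hold for that setting only. With treatment alone edgeR called 0, 8, 40 and 62% of genes changed 2, 4, 8 and 16-fold after simulated doxorubicin, and no unchanged gene among 55 calls. With donor it called 58, 100, 100 and 100%, and 12.3% of 204 calls were unchanged genes. For simulated Nutlin-3 it called 2% and 30% of genes changed 4 and 16-fold with treatment alone, and 98 and 100% with donor, where 10% of 110 calls were unchanged genes. DESeq2 had 3.21% and 5.21% unchanged genes among its calls, and 17.8% and 23.8% with donor. Further tools were the R package data.table (version 1.17.8), Python 3.11.15 and pandas 2.3.3, with figures drawn by matplotlib 3.10.9.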

Results

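RNA sequencing measured gene expression in cultured human pulmonary arterial adventitial fibroblasts, the connective tissue cells of the outer coat of the pulmonary artery. Cells of 2 healthy donors were exposed for 24 h to vehicle, to doxorubicin at 0.5 µg/ml or to Nutlin-3 at 10 µM, which gave 6 libraries in 3 groups of 2. Doxorubicin poisons topoisomerase II and damages DNA, and Nutlin-3 blocks the binding of MDM2 to p53. The comparisons ask which genes respond to genotoxic stress and which respond to p53 activation. Replicates with the same number come from the same donor. Total counts of replicates 1 and 2 were 25402676 and 29703404 for vehicle, 24486872 and 27502575 for doxorubicin, and 29509361 and 28622660 for Nutlin-3. Levels are group means ± SD with n = 2 in CPM, the counts scaled to library size, on which scale 3 counts in a library stand at 0.103 to 0.115. Floors and counting intervals cover counting error alone. Fold changes are log2 values ± SE, with p from edgeR adjusted by Benjamini and Hochberg over 16224 genes, and positions refer to GRCh38. The SE is not an output of edgeR. It was derived as the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. Calls come from the model with treatment alone, and values "with donor" come from the same model with the donor added.

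Donor and treatment each carried much of the variation between libraries. The first principal component held 43.4% of the variance and the second 42.9%. The biological coefficient of variation was 0.495 with treatment alone and 0.192 with donor. Fold changes of the donors had the same sign at 78.8% of genes for doxorubicin, 67.0% for Nutlin-3 and 77.1% for the difference between them.

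After doxorubicin, p53 target genes and replication-dependent histone genes were higher, and the gene group for G2 and mitosis was lower. These list calls came from camera with the preset correlation, and none held with an estimated correlation (adjusted p = 0.390, 0.311 and 0.752). Here and below, the test with an estimated correlation rests on the few residual degrees of freedom. A miss there cannot tell low power from correlation between genes. FDXR, a mitochondrial reductase gene and p53 target (chromosome 17, 74862497 to 74873031), rose from 13.1 ± 1.99 to 244 ± 75.4 CPM, a log2 fold change of 4.22 ± 0.37 (adjusted p = 0.0373). HIST1H2BG, a histone H2B gene (chromosome 6, 26215159 to 26216692), rose from 4.36 ± 0.646 to 132 ± 44.2 CPM, by 4.92 ± 0.33 (adjusted p = 0.0373). BUB1, a spindle checkpoint kinase gene (chromosome 2, 110637698 to 110678114), stood at 2.09 ± 0.671 against 13.2 ± 4.02 CPM, a log2 fold change of -2.66 ± 0.43 (adjusted p = 0.0534, and 0.00979 with donor). In all, 311 of 16224 genes changed, 209 of them higher and 102 lower. With donor the count was 5508, with 2794 higher and 2714 lower, and it held all 311. DESeq2 called 3153 genes, and 5479 with donor. Leaving out any 1 library, or fitting the 2 groups alone, left 0 genes past the threshold in edgeR with treatment alone, with 2732 to 4025 and 3625 genes at an unadjusted p under 0.05. With donor, 2065 and 2472 genes passed without vehicle replicates 2 and 1, and 8367 without doxorubicin replicate 1.

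The p53 targets rose as a group after doxorubicin. Of 35 measured targets, 11 rose and 0 fell. Adjusted over the list alone, 27 rose and 1 fell, and with donor 30 rose and 1 fell over all genes. Their median log2 fold change was 1.93, and camera gave an adjusted p = 8.99e-19, with adjusted p = 0.390 with an estimated correlation. BBC3, which encodes the death-promoting protein PUMA (chromosome 19, 47220822 to 47232766), rose by 2.90 ± 0.19 from 12.3 ± 1.35 to 91.6 ± 0.941 CPM (adjusted p = 0.0373). PLK3, a stress-responsive kinase gene, rose by 2.89 ± 0.23 (adjusted p = 0.0373), and TP53INP1 rose by 2.18 ± 0.20 (adjusted p = 0.0373). The exception, named after its values were seen, was POLK, which encodes a translesion DNA polymerase, at -0.62 (adjusted p = 0.0880, and 0.0188 with donor). MDM2, the ubiquitin ligase gene of the p53 feedback loop, was at 1.31 ± 0.52 (adjusted p = 0.186, and 0.0301 with donor). CDKN1A, the gene of the cell cycle inhibitor p21, was at 1.89 ± 0.41 (adjusted p = 0.0749, and 0.0146 with donor).

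**Figure D1:**
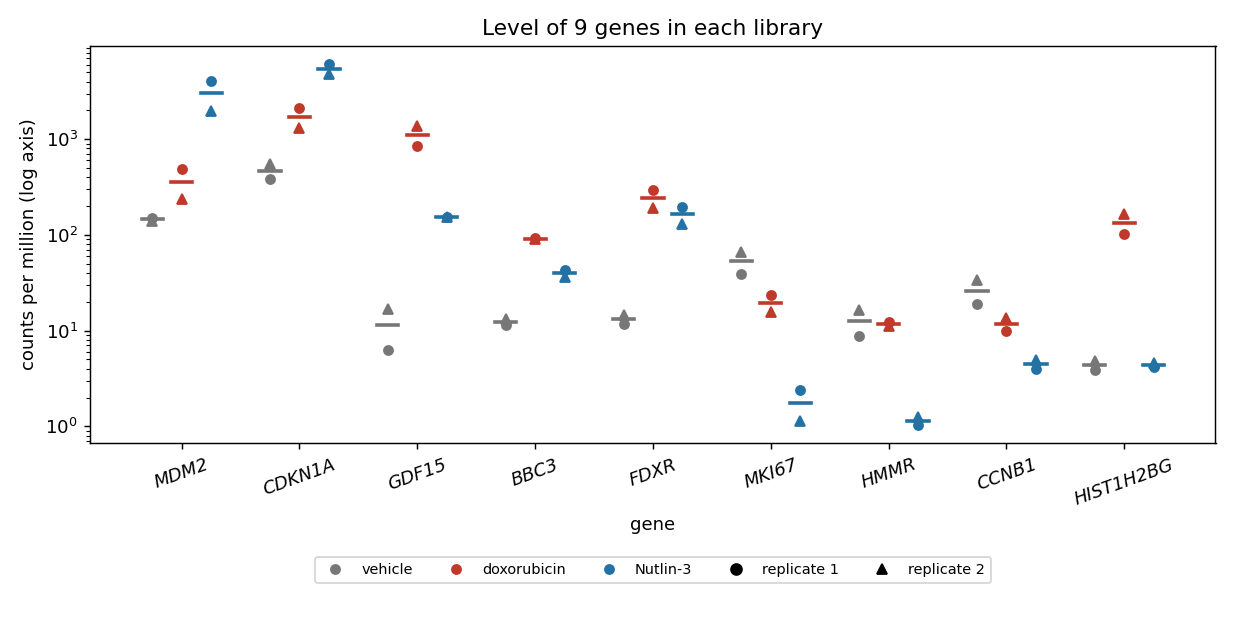
Levels of 9 genes in each of the 6 libraries, in CPM on a log axis; circles are replicate 1, triangles replicate 2 and lines the group means. MDM2 averaged 145 CPM in vehicle, 360 CPM after doxorubicin and 3017 CPM after Nutlin-3, while HIST1H2BG averaged 132 CPM after doxorubicin against 4.36 CPM in vehicle.

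Replication-dependent histone genes, whose transcripts normally peak in S phase, rose after doxorubicin. Of 19 measured genes, 6 rose and 0 fell. Adjusted over the list alone 14 rose, and with donor 15 rose over all genes. The median log2 fold change was 2.94, all 19 fold changes were positive, and camera gave an adjusted p = 6.44e-11 (adjusted p = 0.311 with an estimated correlation). HIST1H3H rose by 4.53 ± 0.43 (adjusted p = 0.0373), HIST1H4H by 3.60 ± 0.36 (adjusted p = 0.0385) and HIST1H2BJ by 3.49 ± 0.32 (adjusted p = 0.0373). Summed over the 71 histone genes in the table, CPM on TMM-scaled library sizes were 3.78-fold and 6.12-fold those of vehicle in the 2 donors after doxorubicin. After Nutlin-3 the same sum was 0.990-fold and 1.02-fold.

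After doxorubicin the 30 genes of G2 and mitosis had a median log2 fold change of -0.95 (camera adjusted p = 6.34e-05, and adjusted p = 0.752 with an estimated correlation), and the donor medians were -0.38 and -1.64. In that list 1 gene rose and 0 fell, against 1 rise and 6 falls adjusted over the list alone, and 1 rise and 10 falls with donor. The gene that rose was PTTG1, which encodes securin, an inhibitor of sister chromatid separation, at 2.00 ± 0.27 (adjusted p = 0.0480). PLK1, a mitotic kinase gene, was at -2.22 ± 0.38 (adjusted p = 0.0567, and 0.0111 with donor), and CENPE, a kinetochore motor gene, at -2.02 ± 0.40 (adjusted p = 0.0674, and 0.0153 with donor). Of 32 DNA replication genes, 3 rose and 0 fell, and the same 3 and 0 counts came adjusted over the list alone, against 4 higher and 3 lower with donor. The list median was 0.02, with donor medians of 0.54 and -0.39 (camera adjusted p = 0.564). PCNA, the sliding clamp of DNA polymerase and also a p53 target, rose by 3.20 ± 0.27 from 47.9 ± 13.8 to 440 ± 7.38 CPM (adjusted p = 0.0373). GINS4 rose by 2.87 ± 0.30 (adjusted p = 0.0392) and TYMS, the thymidylate synthase gene, by 2.73 ± 0.33 (adjusted p = 0.0458). MCM3, a subunit of the replicative helicase, was at -1.50 ± 0.35 (adjusted p = 0.0812, and 0.0177 with donor). The 18 genes of homologous recombination and the Fanconi pathway held no call, 1 higher adjusted over the list alone and 2 higher with donor (median -0.35, donor medians 0.47 and -1.24, camera adjusted p = 0.444).

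**Figure D2:**
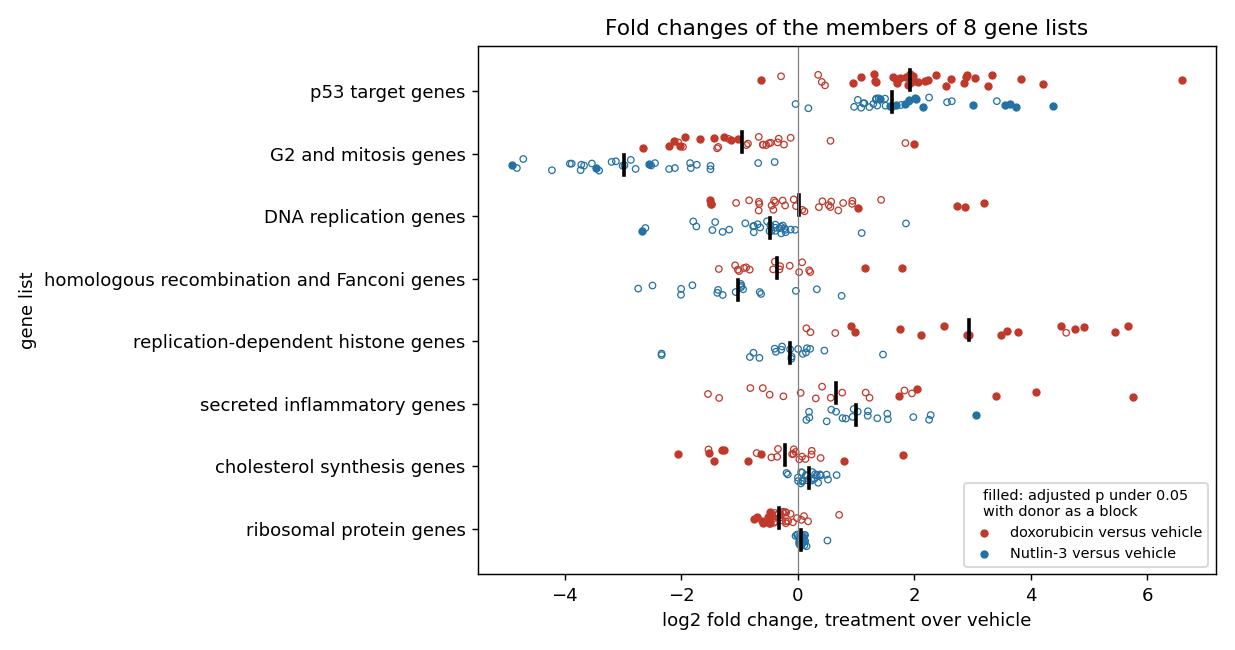
Log2 fold changes of the measured members of 8 gene lists after doxorubicin and after Nutlin-3, each over vehicle; filled points have an adjusted p under 0.05 with donor in the model, and black bars are medians. Histone genes have a median of 2.94 after doxorubicin and -0.13 after Nutlin-3 (-0.11 with genes at 0 counts set to their bounds), and genes of G2 and mitosis have medians of -0.95 and -2.99.

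Among the largest rises after doxorubicin were genes with few or no counts in vehicle. RNASE7, which encodes an antimicrobial ribonuclease (chromosome 14, 21042226 to 21044234), had 0 vehicle counts and was at least 174-fold higher, at 9.52 ± 3.99 CPM (adjusted p = 0.0492). That bound takes 3 counts over the vehicle group as the floor. POU3F1, a POU domain transcription factor gene, rose by 8.40 ± 0.71 to 107 ± 70.0 CPM (adjusted p = 0.0373). PDE4C, a cyclic AMP phosphodiesterase gene, rose by 8.06 ± 1.11 (adjusted p = 0.0480), and NTN1, which encodes the guidance protein netrin-1, rose by 8.02 ± 1.04 (adjusted p = 0.0466). EN2 had 3 vehicle counts and a count ratio of 228 (95% counting interval 77.7 to 1108; adjusted p = 0.0490), HCN4 had 2 and a ratio of 209.5 (57.6 to 1736; adjusted p = 0.0480). GRIN2C, a glutamate receptor subunit gene, rose by 7.47 ± 0.81 (adjusted p = 0.0397).

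The largest falls among genes called with treatment alone were smaller in size. The authors' DESeq2 table lists larger falls for MIR210HG at -4.46 and HIF3A at -4.28. Here both were called with donor but not with treatment alone. FES, a tyrosine kinase gene (chromosome 15, 90883695 to 90895776), went from 5.62 ± 0.369 to 0.578 ± 0.0283 CPM, a log2 fold change of -3.27 ± 0.37 (adjusted p = 0.0405). LRBA, a regulator of vesicle traffic (chromosome 4, 150264531 to 151015727), changed by -3.12 ± 0.22 (adjusted p = 0.0373) from 69.0 ± 4.54 to 7.93 ± 1.77 CPM. RAC3, a small GTPase gene, changed by -2.77 ± 0.28 (adjusted p = 0.0385), and BNC2, a zinc finger gene, by -2.70 ± 0.22 (adjusted p = 0.0373). ANKRD35 followed at -2.55 ± 0.36 (adjusted p = 0.0482), SIGIRR, a brake on interleukin-1 signalling, at -2.54 ± 0.26 (adjusted p = 0.0385) and DMXL2 at -2.43 ± 0.19 (adjusted p = 0.0373). DPYD, the gene of pyrimidine breakdown, changed by -2.42 ± 0.16 (adjusted p = 0.0373) from 52.4 ± 0.407 to 9.76 ± 0.0283 CPM. LRBA, BNC2, DMXL2 and DPYD span 751.2, 461.3, 175.1 and 843.3 kb, and FES, RAC3, ANKRD35 and SIGIRR 12.08, 2.581, 19.31 and 11.74 kb.

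Several smaller gene groups moved with doxorubicin. Of 14 genes of the BCL2 family, which controls mitochondrial cell death, 2 rose and 0 fell, 3 rose adjusted over the list alone, and 5 rose and 1 fell with donor (median 0.74, camera adjusted p = 0.0475, and adjusted p = 0.681 with an estimated correlation). BAK1, a pore-forming member, rose by 1.53 ± 0.22 (adjusted p = 0.0491). Of 23 immediate early genes 1 rose and 1 fell, 4 and 2 adjusted over the list alone, and 12 and 2 with donor (median 0.74, camera adjusted p = 0.0475, and adjusted p = 0.681 with an estimated correlation). ATF3, a stress-induced transcription factor gene, rose by 4.23 ± 0.55 to 109 ± 48.2 CPM (adjusted p = 0.0471), and ZFP36, which promotes decay of unstable mRNA, changed by -1.33 ± 0.17 (adjusted p = 0.0466). Of 24 cholesterol synthesis genes 0 rose and 1 fell, 1 and 4 adjusted over the list alone, and 2 and 7 with donor (median -0.22). Camera placed that list lower (adjusted p = 0.0475, adjusted p = 0.715 with an estimated correlation, and 0.0865 with donor), and SREBF2, its master regulator, changed by -1.31 ± 0.16 (adjusted p = 0.0458). Ribosomal protein genes had a median of -0.32 with 0 calls among 34 and 0 adjusted over the list alone in edgeR, 10 lower with donor (camera adjusted p = 0.00800, and adjusted p = 0.841 with an estimated correlation). RPL3 and RPL4 stood at -0.75 ± 0.28 and -0.70 ± 0.25 (adjusted p = 0.165 and 0.153, and 0.0194 and 0.0156 with donor). Without vehicle replicate 2 ribosomal proteins missed the threshold (adjusted p = 0.157), as did cholesterol synthesis without doxorubicin replicate 1 (0.304), the BCL2 family without any library but vehicle replicate 2 (0.0716 to 0.168), and immediate early genes without any library but doxorubicin replicate 1 or vehicle replicate 2 (0.0859 to 0.282). Fry, which tests whether the genes of a list move on balance 1 way and does not compare them with other genes, called the p53 and histone lists (adjusted p = 0.0209 for each). With donor, fry called both (0.0203 and 0.0163) and also, as higher, the BCL2 family (0.0203), immediate early (0.0163) and interferon-stimulated genes (0.0367), smooth muscle and pericyte markers (0.0455) and leukocyte markers (0.00252). Of the 5 leukocyte markers tested, 2 had 0 counts in vehicle, so the filter favoured a rise in that list.

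Lists tied to fibroblast identity and vessel wall function held few calls after doxorubicin. None of 36 extracellular matrix genes passed in edgeR, by either adjustment, and 1 higher and 9 lower passed with donor (median -0.16, camera adjusted p = 0.230). COL5A2, a fibrillar collagen gene, stood at -0.66 ± 0.20 (adjusted p = 0.120, and 0.0157 with donor). The other lists, each with its tested members, camera adjusted p and calls with donor, were 17 contractile genes (0.564, 5 higher and 1 lower), 30 BMP and TGF-beta pathway genes (0.945, 8 and 7), 24 YAP targets (0.804, 3 and 5), 18 stress response genes (0.736, 2 and 3), 21 interferon-stimulated genes (0.444, 4 and 3) and 20 secreted inflammatory genes (0.159, 5 and 0). Adjusted over the list alone, 1 contractile gene rose and 1 fell, 1 and 2 BMP and TGF-beta pathway genes, 1 and 0 stress response genes, 3 and 0 secreted inflammatory genes, and none in the YAP and interferon lists. Secreted inflammatory genes had a median of 0.66 and passed in camera with donor (adjusted p = 0.0285, and adjusted p = 0.800 with an estimated correlation). LIF, a cytokine of the interleukin-6 family, stood at 5.75 ± 1.05 (adjusted p = 0.0605, and 0.00331 with donor). ENG, the TGF-beta co-receptor endoglin, changed by -1.33 ± 0.19 (adjusted p = 0.0490), and DDIT3, a stress-induced transcription factor gene, rose by 2.52 ± 0.24 (adjusted p = 0.0373). ISG15 stood at 2.27 ± 0.42 (adjusted p = 0.0619, and 0.00433 with donor) and ACTA2, smooth muscle actin, whose locus overlaps FAS on the opposite strand, at 1.21 ± 0.22 (adjusted p = 0.0601, and 0.0128 with donor).

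Markers of other cell types were measured beside these groups. Adventitial fibroblast markers had a median of 0.05 over 17 genes (camera adjusted p = 0.826, 1 higher and 3 lower with donor). Endothelial markers were at a median of -0.64 and a mean of 0.10 over 11 genes (camera adjusted p = 0.564, 0 and 3 with donor), and smooth muscle and pericyte markers at 0.58 over 10 genes (camera adjusted p = 0.159, 3 and 0 with donor). Epithelial markers were at 1.11 over 6 genes (camera adjusted p = 0.444, 2 and 0 with donor) and leukocyte markers at 2.76 over 5 genes (camera adjusted p = 0.159, 3 and 1 with donor). SYNM, which encodes the intermediate filament protein synemin, rose by 4.72 ± 0.46 from 7.89 ± 3.46 to 207 ± 38.1 CPM (adjusted p = 0.0373), the only call with treatment alone in these 5 lists. Adjusted over the list alone, that gene and 2 leukocyte markers passed. The leukocyte gene PTPRC reached 0.658 ± 0.384 CPM from 0 counts, at least 11.8-fold higher (adjusted p = 0.106, and 0.0452 with donor). The leukocyte list has 14 members, of which 5 were tested. LYZ and PTPRC, and the epithelial marker CDH1, had 0 counts in vehicle and after Nutlin-3, so they passed the filter only through the doxorubicin libraries. CD68, at a higher level, was lower after doxorubicin, at 39.8 and 59.7 CPM against 51.9 and 89.2 CPM in vehicle.

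Fold changes after doxorubicin followed the genomic span of genes. Across the 16224 tested genes, Spearman's rho between span and log2 fold change was -0.224, with -0.188 and -0.221 in the 2 donors, and genes are not independent replicates. In the shortest group of 1623 genes, 0.144 to 3.35 kb, the median log2 fold change was 0.49. In the longest, 161.9 to 2298 kb, it was -0.43. With donor, 5.85% of the shortest and 36.1% of the longest genes fell, and 22.0% and 10.8% rose. After Nutlin-3 rho was -0.101, with -0.0334 and -0.136 in the donors, and the medians of the same groups were 0.12 and -0.02. Without vehicle replicate 2 the Nutlin-3 value was -0.0436, without Nutlin-3 replicate 1 it was -0.0661, and no test of the difference between treatments was run.

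**Figure D3:**
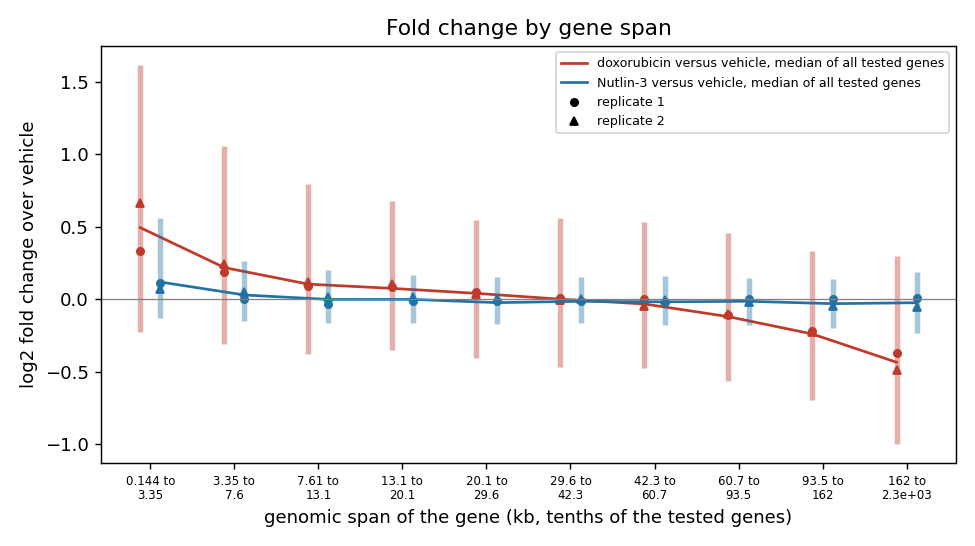
Median log2 fold change over vehicle in 10 groups of tested genes ordered by genomic span in kb, for doxorubicin and Nutlin-3; lines join the medians, vertical bars reach from the lower to the upper quartile, and circles and triangles are replicates 1 and 2. The doxorubicin median runs from 0.49 in the shortest genes to -0.43 in the longest, and the Nutlin-3 median from 0.12 to -0.02.

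Nutlin-3 raised p53 targets and lowered genes of G2 and mitosis as groups in camera with the preset correlation. No single gene passed with treatment alone, and neither list passed with an estimated correlation (camera adjusted p = 0.108 and 0.175). The 35 p53 targets had a median log2 fold change of 1.62, and 34 were positive. The 30 genes of G2 and mitosis had a median of -2.99, and all 30 were negative. MDM2 (chromosome 12, 68808176 to 68850686) stood at 3017 ± 1493 CPM against 145 ± 5.55 in vehicle, a log2 fold change of 4.38 ± 0.58 (adjusted p = 0.292, and 0.0352 with donor). MKI67, a marker of dividing cells (chromosome 10, 128096659 to 128126385), stood at 1.76 ± 0.870 against 53.2 ± 19.6 CPM, at -4.91 ± 0.55 (adjusted p = 0.248, and 0.0489 with donor). In edgeR with treatment alone 0 genes changed, with 614 at an unadjusted p under 0.05. An even spread of p gives 811, but this model leaves the difference between donors in its error, so its p run high. With donor 52 changed, 47 higher and 5 lower, and 1526 had an unadjusted p under 0.05. DESeq2 called 247 genes, 46 of them among the 52, and 525 with donor, which held all 52. Leaving out 1 library moved the edgeR count with donor to 18 and 96 without Nutlin-3 replicates 1 and 2, 117 and 192 without vehicle replicates 1 and 2, and 532 and 636 without doxorubicin replicates 1 and 2.

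All 35 measured p53 targets missed the all-gene threshold after Nutlin-3 with treatment alone, 32 rose and 0 fell adjusted over the list alone, and 13 rose with donor. Camera gave an adjusted p = 8.48e-83, with adjusted p = 0.108 with an estimated correlation, and fry gave 0.0490 (0.0695 with donor). CDKN1A (chromosome 6, 36676460 to 36687339) stood at 5464 ± 912 CPM against 466 ± 115, at 3.55 ± 0.43 (adjusted p = 0.249, and 0.0423 with donor). FDXR stood at 3.64 ± 0.36 (adjusted p = 0.245, and 0.0352 with donor) and TP53INP1 at 1.91 ± 0.19 (0.245, and 0.0238). GDF15, a secreted stress factor, stood at 3.74 ± 0.57, with 153 ± 0.871 against 11.5 ± 7.33 CPM (adjusted p = 0.305, and 0.0423 with donor). Outside the list, the rule for naming genes took no gene with treatment alone, and the same rule applied with donor was chosen after the values were seen. It took KANK3 at 5.33 ± 0.66, TSPAN11 at 4.68 ± 0.37, NTN1 at 4.17 ± 0.91, CYFIP2 at 4.08 ± 0.31, TYMSOS at 4.13 ± 0.66 and GAS6-AS1 at 3.60 ± 0.85 as higher, with adjusted p from 0.0209 to 0.0423 with donor. TYMSOS and GAS6-AS1 overlap TYMS and GAS6 on the opposite strand.

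Cell cycle lists were lower after Nutlin-3. Of the 30 genes of G2 and mitosis 0 passed over all genes in edgeR, 27 fell adjusted over the list alone, and 3 fell with donor (camera adjusted p = 3.13e-81, and adjusted p = 0.175 with an estimated correlation). The donor medians were -2.38 and -3.41. The estimated correlation between genes of this list was 0.672, and the list missed the threshold in fry (adjusted p = 0.106, and 0.130 with donor). HMMR, a spindle-associated gene, stood at -3.47 ± 0.42 (adjusted p = 0.249, and 0.0423 with donor), and CCNB1, the cyclin B1 gene, at -2.55 ± 0.40 (0.305, and 0.0372). DNA replication genes had a median of -0.48 over 32 genes, 1 higher and 1 lower adjusted over the list alone and 1 lower with donor (camera adjusted p = 5.58e-08, and adjusted p = 0.348 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, was at -2.67 ± 0.48 (adjusted p = 0.363, and 0.0352 with donor), while PCNA was at 1.86 ± 0.26 (0.298, and 0.0504). Homologous recombination and Fanconi genes had a median of -1.02 over 18 genes and no gene call by any of these counts (camera adjusted p = 2.33e-10, and adjusted p = 0.348 with an estimated correlation). In fry that list and the DNA replication list missed the threshold (adjusted p = 0.445 for each, and 0.474 for each with donor). The fifth gene lower with donor was STMN1, a microtubule regulator, at -1.83 ± 0.31 (adjusted p = 0.339, and 0.0423 with donor).

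Other lists passed camera after Nutlin-3 with few single genes. All 20 secreted inflammatory genes had positive fold changes, with a median of 0.99 and donor medians of 1.33 and 0.20 (camera adjusted p = 6.12e-05, and adjusted p = 0.348 with an estimated correlation). Without Nutlin-3 replicate 1 the list stood at adjusted p = 0.760. None of its genes passed adjusted over the list alone, and LIF stood at 3.07 ± 0.94 (adjusted p = 0.946, and 0.0352 with donor). BCL2 family genes had a median of 0.32, or 0.15 with the 1 gene at 0 counts in 1 group set to its bound (camera adjusted p = 7.62e-04, and adjusted p = 0.270 with an estimated correlation). In that list 3 rose adjusted over the list alone and 1 with donor, BBC3 at 1.69 ± 0.18 (adjusted p = 0.248, and 0.0423 with donor). Immediate early genes were at a median of 0.33 (camera adjusted p = 0.0185, and adjusted p = 0.348 with an estimated correlation), and cholesterol synthesis genes at 0.20 (0.0457, and adjusted p = 0.473 with an estimated correlation). Without Nutlin-3 replicate 2 or vehicle replicate 1, the BCL2 family (adjusted p = 0.0738 and 0.0799) and immediate early genes (0.507 and 0.552) missed the threshold, and cholesterol synthesis missed it without any vehicle or Nutlin-3 library (0.0858 to 0.267). With donor, interferon-stimulated genes and adventitial fibroblast markers also passed as lower (adjusted p = 0.0267 and 0.00754, and adjusted p = 0.420 for each with an estimated correlation), with medians of -0.40, or -0.36 with the 1 gene at 0 counts set to its bound, and -0.24. The remaining lists missed the threshold, with camera adjusted p of 0.426 for histones, 0.343 for ribosomal proteins, 0.259 for extracellular matrix, 0.793 for contractile and for BMP and TGF-beta pathway genes, and 0.920 for stress response, YAP target and leukocyte genes. The values were 0.125 for endothelial, 0.281 for smooth muscle and pericyte and 0.0584 for epithelial markers.

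Set against Nutlin-3, doxorubicin left histone genes and genes of G2 and mitosis higher, and MDM2 and CDKN1A lower. The 2 lists passed in camera with the preset correlation but not with an estimated correlation (adjusted p = 0.211 and 0.633). HIST1H2BG stood at 132 ± 44.2 against 4.38 ± 0.347 CPM, a log2 difference of 4.92 ± 0.33 (adjusted p = 0.0915, and 0.00800 with donor). MDM2 stood at 360 ± 174 against 3017 ± 1493 CPM, at -3.07 ± 0.55 (adjusted p = 0.0973, and 0.00934 with donor), and CDKN1A at 1723 ± 588 against 5464 ± 912 CPM, at -1.67 ± 0.40 (0.123, and 0.0230). With treatment alone 0 genes changed in edgeR, with 3656 at an unadjusted p under 0.05 where an even spread of p gives 811. With donor 4256 changed, 2032 higher and 2224 lower. DESeq2 called 2226 genes, of which 2141 were among the 4256, and 4630 with donor. With donor 867 and 551 genes passed without Nutlin-3 replicates 1 and 2, and 7512 without doxorubicin replicate 1.

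The p53 targets differed between the treatments in both directions. Among 35, 3 were higher and 2 lower with doxorubicin adjusted over the list alone, 7 and 5 with donor over all genes, and the median difference was 0.29 (camera adjusted p = 0.506). GDF15 was higher with doxorubicin at 2.86 ± 0.55, with 1109 ± 372 against 153 ± 0.871 CPM (adjusted p = 0.102, and 0.0116 with donor), and BBC3 at 1.21 ± 0.18 (0.0960, and 0.0116). CCNG1, the cyclin G1 gene, was at -1.43 ± 0.26 (adjusted p = 0.0973, and 0.0106 with donor). Histone genes had a median of 2.52, 16 of 19 higher adjusted over the list alone and 16 with donor (camera adjusted p = 8.57e-14, and adjusted p = 0.211 with an estimated correlation, fry 0.0391, and 0.0452 with donor). With donor fry also called interferon-stimulated and immediate early genes, adventitial fibroblast markers, and smooth muscle and pericyte markers as higher with doxorubicin (adjusted p = 0.0452 for each). Genes of G2 and mitosis had a median of 1.98, 22 of 30 higher adjusted over the list alone and 19 with donor (camera adjusted p = 1.40e-11, and adjusted p = 0.633 with an estimated correlation). HMMR stood at 3.35 ± 0.42 (adjusted p = 0.0960, and 0.00943 with donor) and MKI67 at 3.47 ± 0.52 (0.0960, and 0.0138). DNA replication genes had a median of 0.81, 7 higher adjusted over the list alone, and 9 higher and 2 lower with donor (camera adjusted p = 5.79e-04, and adjusted p = 0.753 with an estimated correlation).

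Further lists separated the treatments in camera. Cholesterol synthesis genes were lower with doxorubicin at a median of -0.64, 1 higher and 5 lower adjusted over the list alone and 2 and 7 with donor (adjusted p = 8.06e-04, and adjusted p = 0.633 with an estimated correlation). SREBF2 stood at -1.61 ± 0.16 (adjusted p = 0.0915, and 0.00800 with donor). Ribosomal protein genes were at -0.39 with 0 calls adjusted over the list alone in edgeR and 12 lower with donor (adjusted p = 3.10e-04, and adjusted p = 0.753 with an estimated correlation). Smooth muscle and pericyte markers were at 1.33 with 4 of 10 higher with donor, SYNM at 4.52 ± 0.45 among them (camera adjusted p = 0.0251, and adjusted p = 0.633 with an estimated correlation). That list missed the threshold without doxorubicin replicate 2 (0.129) or Nutlin-3 replicate 1 (0.0888). Homologous recombination and Fanconi genes were at 0.78 (adjusted p = 0.0326, adjusted p = 0.753 with an estimated correlation, and 0.0846 with donor), and the call ended without any library but doxorubicin replicate 2 (0.0725 to 0.708). Among the largest differences with donor, by the naming rule applied there after the values were seen, was NOTO, a homeobox gene at 0 counts after Nutlin-3 and at least 232-fold higher with doxorubicin (adjusted p = 0.105, and 0.0110 with donor). RNASE7 had 1 count after Nutlin-3 and a ratio of 530 (95% counting interval 94.7 to 20960), and ZCCHC12 had 2 and a ratio of 301 (83.0 to 2493). KLC3 was at 7.77 ± 2.02 and CRTAC1 at 7.36 ± 1.21 (adjusted p from 0.00800 to 0.00986 with donor for these 4 genes). Lower with doxorubicin were MIR210HG at -4.56 ± 1.52, the metallothionein genes MT1X at -4.12 ± 1.03, MT1E at -3.31 ± 1.19 and MT2A at -3.24 ± 0.85, and HIF3A at -3.77 ± 0.96, with adjusted p from 0.00800 to 0.0443 with donor. The remaining 14 lists, p53 targets included, had camera adjusted p of 0.0673 or more.

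Genes called with donor after Nutlin-3 were largely called after doxorubicin too. With treatment alone 0 genes changed under both treatments in edgeR, since 0 changed after Nutlin-3, against 174 in DESeq2. With donor 49 of the 52 Nutlin-3 genes changed in the same direction after doxorubicin, 47 higher where independent lists give 8.09 and 2 lower where they give 0.836, and 0 changed in opposite directions. Both comparisons share the vehicle libraries. With all 6 libraries, vehicle included, simulated without treatment effects, a mean of 0.3 such genes and at most 2 came over 20 simulations. The covariance of the 2 sets of fold changes was 0.324 across genes against 0.0692 in those simulations, while their correlation was 0.465 against 0.504. Doxorubicin in 1 donor and Nutlin-3 in the other share no vehicle library, and their fold changes correlated across genes at 0.302 and 0.352, with covariances of 0.220 and 0.329, where genes are not independent replicates. Controls could not be split into sets of 2 libraries for the calls themselves, so part of the shared calls may come from the shared vehicle libraries. Of the 52 genes, 18 differed toward a larger change with doxorubicin and 7 toward a larger change with Nutlin-3 in the test of the difference with donor. CYFIP2, KANK3 and FDXR had no such difference (adjusted p = 0.139, 0.976 and 0.146 with donor).

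The authors' own DESeq2 tables list genes at an adjusted p under 0.05. Their doxorubicin table holds 1726 genes, 1162 higher and 564 lower, of which 1711 were tested here and had the same direction. Of these, 310 changed with treatment alone and 1692 with donor. The Nutlin-3 table holds 217 genes, 142 higher and 75 lower, all tested here with the same direction, and 46 changed with donor against 0 with treatment alone. Log2 fold changes in those tables and here correlated across the shared genes at 0.999 for doxorubicin and 1.00 for Nutlin-3. MDM2 is listed there at 4.36 after Nutlin-3, and FDXR at 4.22 after doxorubicin.

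More genes were detected after doxorubicin. Genes with at least 1 count numbered 22139 and 21307 after doxorubicin, 18670 and 17932 after Nutlin-3, and 18135 and 17775 with vehicle. Thinned to the smallest library, doxorubicin exceeded vehicle by 4046 and 3523 genes in the 2 donors, and Nutlin-3 by 357 and 199. Of 4116 protein-coding genes without a vehicle count, leaving out the olfactory, taste and keratin-associated families, 1196 had a count in both doxorubicin libraries (29.1%, 95% Clopper-Pearson interval 27.7 to 30.5) and 72 in both Nutlin-3 libraries (1.75%, 1.37 to 2.20). The intervals take genes as independent, which they are not, and cover no spread between donors or libraries. A level of 1 CPM was reached by 60 of these 4116 genes after doxorubicin and by 6 after Nutlin-3.

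**Figure D4:**
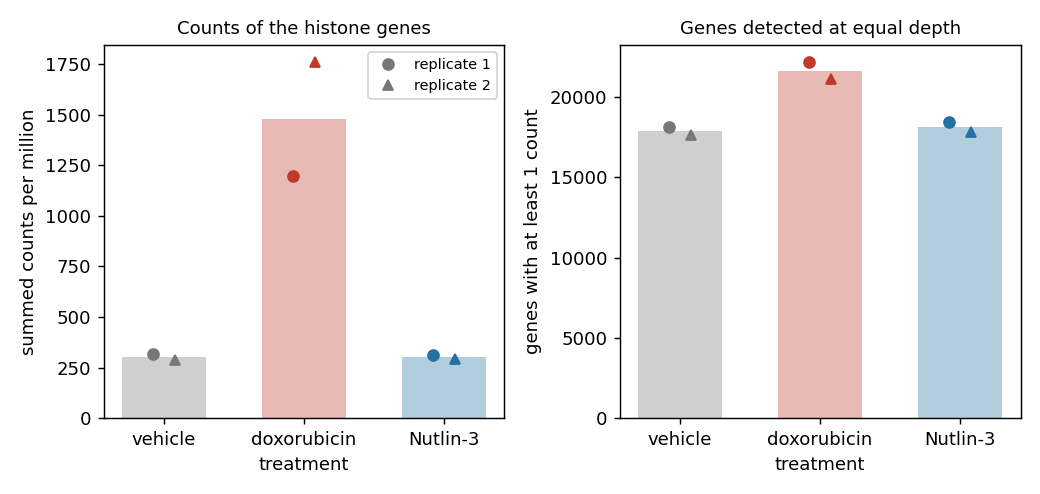
Left, CPM summed over 71 histone genes in each library; right, genes with at least 1 count after thinning to the smallest library. Bars are means of 2 replicates (circle, replicate 1; triangle, replicate 2), and the doxorubicin libraries hold 3523 and 4046 more detected genes than the vehicle libraries of the same donors.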

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

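DESeq2 with donor, and the donor model with a library left out, with an estimated correlation or in fry, were chosen after seeing the data. Genes changed after doxorubicin (311) numbered 596 with at least 10 counts in every library of a group, 3153 in DESeq2, 5508 with donor, 5479 in DESeq2 with donor, and 0 at an adjusted p under 0.01. In edgeR they numbered 0 with only the 2 groups compared (3625 at an unadjusted p under 0.05) and 0 to 0 with any 1 library left out (2732 to 4025). Other scalings, no filter and a 2-fold minimum gave 297 to 340. The donor model gave 8367 and 6481 without doxorubicin replicates 1 and 2, 4157 and 4425 without Nutlin-3 replicates 1 and 2, and 2472 and 2065 without vehicle replicates 1 and 2. For Nutlin-3 (0 in edgeR, 614 at an unadjusted p under 0.05), DESeq2 gave 247, the donor model 52 and DESeq2 with donor 525. In the same order of libraries left out, the donor model gave 532, 636, 18, 96, 117 and 192. Between the treatments (0 in edgeR, 3656 at an unadjusted p under 0.05), DESeq2 gave 2226, the donor model 4256 and DESeq2 with donor 4630, and with libraries left out 7512, 5458, 867, 551, 3687 and 3995. Genes changed by both treatments (0) numbered 174 in DESeq2 and 49 with donor. Lists changed after doxorubicin (7), after Nutlin-3 (8) and between treatments (7) numbered 0, 0 and 0 with an estimated correlation, with or without donor, 2, 1 and 1 in fry, 7, 0 and 5 in fry with donor, and 5 to 7, 5 to 10 and 5 to 9 with a library left out. Leaving out Nutlin-3 replicate 2 gave the 5 of Nutlin-3. The span correlation after doxorubicin (-0.224) was -0.156 without a filter, -0.188 with exonic length and -0.217 to -0.179 with a library left out. After Nutlin-3 (-0.101) it was -0.101 to -0.0436 with a library left out. In these fits the lone library of a group was assumed to vary like the others. The fewer libraries leave fewer residual degrees of freedom; for the other differences the cause was not tested. CSPG4 (-0.35) and SYNPO2 (-0.32) reversed after doxorubicin without doxorubicin replicate 2, and neither was called. With other libraries left out these values reached 6.8 for CSPG4 and 0.90 for SYNPO2. No list reversed. Over the alternatives run, 7 lists after doxorubicin kept direction and call in 55 results and lost the call in 36, 8 after Nutlin-3 in 63 and 41, and 7 between treatments in 57 and 34. Of the results for 78 named genes after doxorubicin 733 kept both, 240 lost the call and 114 gained it, for 36 genes after Nutlin-3 432 kept both and 72 gained a call, and for 39 between treatments 436 and 110. Among lists in camera and genes named in the comparisons, the donor changed no other call than those printed there. The scalings moved the median of all genes by at most 0.04 on the log2 scale. With 2 libraries in a group, changes of 2 to 4-fold were mostly below what the treatment-only test called in simulated data.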

Other observations

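The tests of p53 activation for long genes, of S phase for histones and of background as the source of all added counts, and the choice of the claudin, protocadherin and metallothionein families, were made after the results were seen. No test of a family as a set was run. Of 13 claudin genes, which build tight junctions, 8 rose and 1 fell with donor after doxorubicin and 4 passed in neither edgeR model, with a median log2 fold change of 2.68 against 0.00 after Nutlin-3. CLDN16 and CLDN18 had 0 counts in vehicle and after Nutlin-3, and CLDN9 and CLDN6 had 1 and 2 vehicle counts. The filter thus favoured a rise in this family, in its median and in its calls. With treatment alone 0 claudin, protocadherin or metallothionein genes passed in edgeR after doxorubicin, with 8, 24 and 2 at an unadjusted p under 0.05, and 6, 24 and 1 passed in DESeq2. CLDN1 stood at 81.4 ± 15.3 CPM against 0.204 ± 0.185 in vehicle, a log2 fold change of 8.61 ± 1.53 (adjusted p = 0.0597, and 0.00565 with donor), and CLDN12 was the member that fell, at -0.79 ± 0.20 (0.0880, and 0.0261).

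Of 59 protocadherin genes, which encode adhesion proteins, 24 fell and 4 rose with donor after doxorubicin, with medians of -0.78 after doxorubicin and 0.09 after Nutlin-3. Of the 24, 22 lie in the PCDHG cluster, with log2 fold changes from -0.91 to -0.56. PCDHGA12 was at -0.56 ± 0.23 (adjusted p = 0.193, and 0.0202 with donor) and PCDH19 at 4.75 ± 0.92 (0.0660, and 0.0145). Genes of that cluster overlap and share exons, so their counts are not independent and stand for little more than 1 locus. Metallothionein genes, which encode metal-binding proteins, had a median of -2.32 after doxorubicin, with 2 of 6 lower with donor, and 0.55 after Nutlin-3, where 0 passed with donor in edgeR, 2 at an unadjusted p under 0.05, and 2 in DESeq2 with donor. MT2A stood at 409 ± 312 CPM after doxorubicin, 3864 ± 854 after Nutlin-3 and 2140 ± 1535 in vehicle.

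Long genes were lower after doxorubicin. Loss of spliced RNA by degradation would follow exonic length, but rho with span given exonic length was -0.117 and -0.131 in the donors, and -0.0488 and -0.0667 for exonic length given span, which argues against it as the whole source. GC content and low counts are argued against by rho of -0.152 in the weakest of 5 groups of like GC content, and of -0.235 in the weaker donor for the upper 8112 genes by expression, though in the group of highest GC content replicate 1 alone gave -0.0912. By rho alone activation of p53 stays open, since rho after Nutlin-3 was -0.136 in 1 donor and -0.0334 in the other. In the longest group of genes, the donor medians were 0.01 and -0.05 after Nutlin-3 against -0.37 and -0.49 after doxorubicin. For that group these values argue against p53 activation, as far as Nutlin-3 stands for it, as the whole source of the fall. Impaired transcription of long genes through topoisomerase poisoning may be a source. That hypothesis was the reason, fixed before the data were examined, for setting fold changes against span, and it was not itself tested.

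Histone transcripts were higher after doxorubicin. Reads moved between near-identical copies would leave their sum unchanged, but the summed CPM were 3.78-fold and 6.12-fold those of vehicle. More cells in S phase would raise DNA replication genes as well, and their donor medians over vehicle were 0.54 and -0.39. After Nutlin-3 these medians were -0.23 and -0.74, so a fall shared with p53 activation could hide a rise. Set against Nutlin-3, they were 0.86 and 0.72 with doxorubicin. The values over vehicle therefore cannot decide, and more cells in S phase stays open. Better capture of RNA without a poly(A) tail cannot be told apart, since only 4 other such RNAs (RMRP, RPPH1, SCARNA13 and SCARNA17) were tested, all at low counts, with medians of 0.15 and 0.78. Polyadenylated histone transcripts may be another source, which was not tested.

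More genes were detected after doxorubicin. Depth is argued against, since thinned libraries kept 3523 and 4046 more genes than vehicle. Evenly spread background reads, such as genomic DNA, would also reach olfactory, taste and keratin-associated genes. Of 466 such genes without a vehicle count, 16 (3.43%) were seen in both doxorubicin libraries, against 2134 of 16032 other genes (13.3%). The 95% interval of the difference, with genes taken as independent, was -11.7 to -8.03 percentage points. The difference was short of the bound set beforehand, so part of the excess stays open to such background. As the source of all added counts it is argued against by counts per exonic kb in other silent protein-coding genes of 7.93 and 8.23 times those of the silent families, where even background would give similar densities. The ratios were 6.86 and 9.49 after Nutlin-3, so they do not set doxorubicin apart. The families held 131 and 104 counts after doxorubicin against 15 and 4 after Nutlin-3, and the other silent protein-coding genes 15380 and 12664 against 1524 and 562, so both sets were higher about in proportion. Some even background may be present, a technical source that raises both sets in proportion was not tested and stays open, and wider transcription after doxorubicin remains a hypothesis.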
